A study of Mus musculus with 5 samples.

How the data were processed

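Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in lineage-depleted bone marrow of mice. The cells were haematopoietic stem and progenitor cells (HSPC) per the labels. All 5 libraries came from mice with Mx1-Cre and the inv(16) allele that had received PIPC, a synthetic double-stranded RNA that evokes interferon and so switches Mx1-Cre on. Of the 5 libraries, 2 were heterozygous for Smc3 (Smc3-het) and 3 had both Smc3 alleles (Smc3-wt), and groups and replicate numbers were taken from the sample titles. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries, which may be technical.

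The authors aligned reads with Bowtie2 to mm10 and called peaks with MACS2, per the submitters' processing notes; versions are not given in the sources used here. The peak names in the deposited lists show paired-end calling after removal of mitochondrial reads, with 1 list per library and no pooling. Whether duplicates or artefact-prone regions were removed is not given in the sources used here. The deposited lists hold, for each peak, its interval, the summit coverage signal as a fragment pileup in whole numbers, and a fold enrichment, which per the file headers is the ratio of pileup to the local background of the same library. The headers of 2 further columns were lost, and by their order and values these deposited columns are the −log10 p and −log10 q of each peak. The lowest −log10 q was between 1.30 and 1.31 in every deposited list, the value of a q threshold of 0.05. These scores are the authors' own values for each peak and served mainly to rank, filter or describe peaks within a list. Values drawn from them were also set side by side between libraries. These were background coverage, pileup over background, the lowest scores of the lists and peak counts above a q threshold.

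Peaks on chromosomes 1 to 19, X and Y were kept and overlapping intervals of a library were merged. The number of mapped fragments per library was not used here, and the depth is therefore described by background coverage. It was solved from pileup and fold with the pseudocount of 1 that MACS2 adds, as the commonest value in each list, which was also the lowest. It was the value of 19.8% of peaks in Smc3-het replicate 1, 43.1% in Smc3-het replicate 2 and 46.9%, 59.2% and 59.2% in Smc3-wt replicates 1, 2 and 3. Because the lists differed in length, peak sets were compared in equal-size lists, the 26885 strongest peaks of each library by −log10 p, which is the length of the shortest list. Their lowest −log10 p was 3.47 and 5.66 in Smc3-het replicates 1 and 2, and 9.84, 10.4 and 14.4 in Smc3-wt replicates 1, 2 and 3. Equal-size lists thus reach weaker peaks in Smc3-het. Regions were the union of intervals that overlapped by at least 1 bp. The gene table used was of assembly GRCm38.p6, the same build as mm10, with 21883 protein-coding genes. It gives start and end of each gene but neither strand nor exons, so the planned promoter class was replaced by gene ends, within 1 kb of either end of a protein-coding gene, and exons and introns were not told apart. A promoter inside a longer annotated span is missed by this measure. Motif shares had been planned and were not run, since no genome sequence was used here.

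The comparison was Smc3-het against Smc3-wt throughout. Group means were compared with two-sided exact permutation tests over the 10 splits of 5 libraries into 2 and 3, whose smallest possible p is 0.2, so no difference here could pass a threshold of 0.05. With groups of 2 and 3, chance gives non-overlapping values in 20% of measures. For regions and gene ends found in every library of one genotype and in none of the other, the same counts were made for the other 9 splits. Before the data were examined, 16 gene lists were fixed, of which 262 of 264 member genes were in the table as protein-coding; Mx1 and Mx2 were annotated as transcribed pseudogenes. For each list, the share of genes with a peak at an end and the number of peaks within the genes and 20 kb on each side, where a peak near several members counts for each, were compared, with Benjamini-Hochberg adjustment over the 16 lists. Each difference was also placed among 10000 random lists, which describes these libraries and is not a test across mice. Lists were matched on the number of libraries with a peak at an end for gene ends, and on the binned number of peaks for loci. The rule for named genes, also fixed beforehand, took the genes nearest to the separating regions, within 100 kb and ranked by the lowest percentile within any list holding the region, 12 in each direction, of which 1 is not reported here. It further took list members whose gene end separated the genotypes, otherwise up to 4 members per list in the order written, and Fli1, Smc3, Runx1, Cbfb and Myh11. Wilson 95% intervals of shares cover counting error only.

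The alternatives were stricter q thresholds (−log10 q of at least 5 or 10), equal-size lists of 13442 peaks or full lists, ranking by fold, an overlap of 50% of the merged region, windows of 500 bp around summits, gene-end windows of 500 bp or 2.5 kb, loci extended by 50 kb, Fli1 extended by 20 kb, lists as deposited, each library left out in turn and a replicate block. The q thresholds also shortened the equal-size lists, to 17309 and 9947 peaks, so they are not separate from list size. The replicate block left out Smc3-wt replicate 3 and paired the other libraries by number. Except for similarity within genotypes, it repeats the values without that library and is not a separate alternative. Added after the data were seen were the analysis without chromosomes X and Y, without peaks over a pileup of 1000, with 500 bp windows at loci, with each peak counted once per list, and without the 2 libraries with peaks at Y-linked genes. The overlap step was tested on simulated lists over the 56749 regions, where 200 of 200 planted Smc3-het regions and 200 of 200 planted Smc3-wt regions were recovered. Planted regions were set in every library of a group and in none of the other, so this checks the overlap code alone. It says nothing of how many regions separate the groups without a genotype effect. In a simulation over 21883 genes, 5.5% of 200 random lists fell beyond the 2.5 and 97.5 percentiles of matched lists. Random and matched lists drew genes independently, whereas some fixed lists hold neighbours that share peaks, such as Pf4 and Ppbp. For those lists the percentiles may be too extreme. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.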

Results

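Open chromatin was profiled by bulk ATAC-seq in HSPC from the bone marrow of inv(16) mice. In human acute myeloid leukaemia the inversion is a recurrent lesion that fuses CBFB, a subunit of the core binding factor, to MYH11, a smooth muscle myosin gene. In the mouse Cbfb and Myh11 lie on different chromosomes, 8 and 16, so an inversion within a chromosome cannot join them. Smc3 encodes a subunit of cohesin, the ring complex that holds DNA loops. The series title places the question in how cohesin haploinsufficiency and inv(16) act together on Fli1 programs, and the 5 peak lists allow 1 comparison, 2 Smc3-het against 3 Smc3-wt libraries. Background coverage was 3.59 and 2.92 fragments per base in Smc3-het replicates 1 and 2, and 2.74, 1.93 and 3.02 in Smc3-wt replicates 1, 2 and 3.

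Among Smc3 and the genes tied to the core binding factor, Smc3, Runx1 and Cbfb had a peak at a gene end in 5 of 5 libraries. The mouse gene Myh11 had one in Smc3-het replicate 2 alone in equal-size lists. For Smc3 (chromosome 19, 53600396 to 53645831), a peak list cannot show the loss of 1 allele, so this checks no label. Runx1, the DNA-binding partner of Cbfb (chromosome 16, 92601466 to 92826074), had, in equal-size lists, 12 and 8 peaks within the gene in Smc3-het and 8, 6 and 8 in Smc3-wt libraries. Cbfb (chromosome 8, 105170674 to 105217989) had 1 or 2 peaks in the gene in each. Myh11 (chromosome 16, 14194527 to 14292188) had 3 peaks in Smc3-het replicate 2 and 0 in the other libraries. The exact permutation p was 0.6 for Runx1, 1 for Cbfb and 0.8 for Myh11 (two-sided, n = 2 and 3). Full lists, longer in Smc3-wt, turned the direction at all 3. Runx1 then had 12 and 10 peaks against 20, 24 and 34, Cbfb 2 and 1 against 4, 2 and 2, and Myh11 0 and 4 against 3, 7 and 7.

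The Smc3-het lists were shorter than every Smc3-wt list. They held 26885 and 36467 unique peaks, against 65880, 102822 and 121224 in Smc3-wt, or 31676 ± 6776 (SD, n = 2) against 96642 ± 28185 (SD, n = 3), 3.05-fold fewer. Accessible length was 18.1 ± 3.61 Mb (SD, n = 2) against 52.0 ± 14.3 Mb (SD, n = 3), 2.88-fold less, at mean peak widths of 571 and 541 bp. Both differences had the smallest p the design allows, 0.2 (two-sided exact permutation test). The lists also differed in strength: the median summit pileup over a library's own background, in regions called in 5 of 5 libraries, was 11.4 and 14.4 in Smc3-het and 25.1, 26.5 and 33.4 in Smc3-wt libraries. With −log10 q of at least 10 the difference was −13439 peaks in place of −64966, and −12.0 Mb in place of −33.9 Mb.

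**Figure D1:**
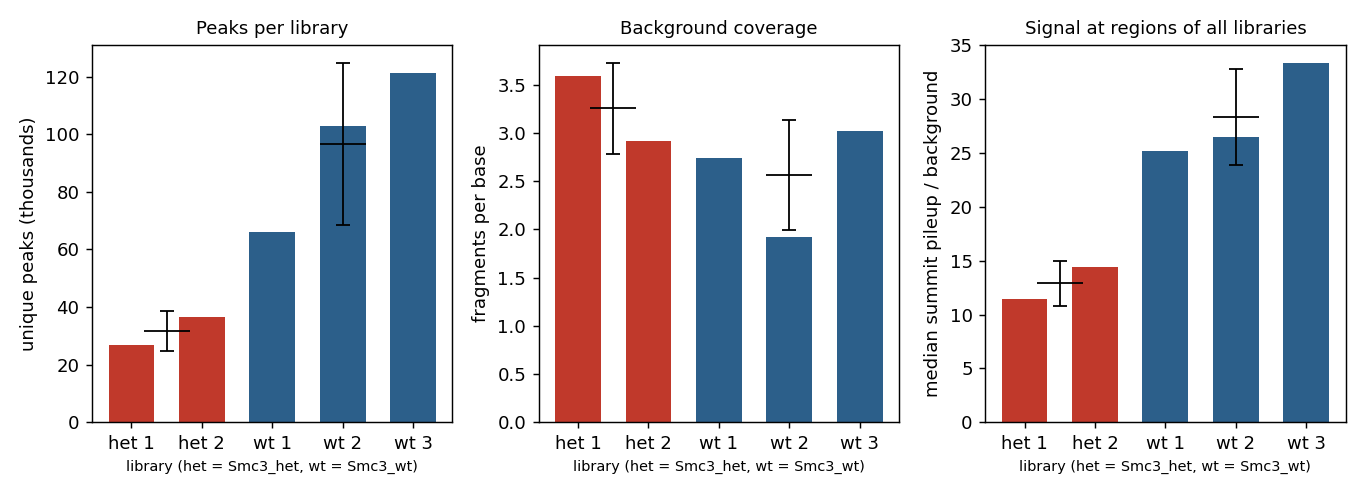
Unique peaks (in units of 1000), background coverage (fragments per base) and median summit pileup over background at regions called in 5 of 5 libraries, as 1 bar per library, with group mean and SD in black (Smc3-het red, n = 2; Smc3-wt blue, n = 3). The Smc3-het bars are the lowest for peaks, 26885 and 36467, and for signal over background, 11.4 and 14.4, but not for background coverage, 3.59 and 2.92.

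In equal-size lists the shares of peaks at gene ends, in gene bodies and between genes differed by under 1 percentage point between genotypes. Gene ends held 35.2% ± 0.402 (SD, n = 2) of Smc3-het and 34.7% ± 0.244 (SD, n = 3) of Smc3-wt peaks, gene bodies 36.0% ± 1.20 and 36.7% ± 0.960, and the space between genes 28.8% ± 1.60 and 28.6% ± 1.17. The two-sided exact permutation p was 0.2 for gene ends, 0.4 for gene bodies and 0.8 for the space between genes. Within a single library the Wilson 95% interval of the gene-end share was wider than the difference of 0.523 points, at 34.9% to 36.1% in Smc3-het replicate 1. The gene-end share was higher in Smc3-het under every alternative run, by 0.238 points without Smc3-het replicate 1, 1.60 points with equal-size lists of 13442 peaks and 17.5 points in full lists, where the Smc3-het lists were shorter.

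Accessible regions common to the 5 libraries were mostly gene ends. Of 56749 regions in equal-size lists, 12321 were called in 5 of 5 libraries, and 61.4% of these lay at a gene end. Of protein-coding genes, 9021 had a gene-end peak in every library. The mean Jaccard index (shared over total bp) was 0.453 within and 0.393 between genotypes, a difference of 0.0603, the highest of the 10 splits, with 0.0222 the next (two-sided exact permutation p 0.2). In equal-size lists the closest libraries were Smc3-wt replicates 1 and 3 at 0.516, while the Smc3-het pair, at 0.397, was less alike than Smc3-het replicate 2 was to any Smc3-wt library (0.406 to 0.426). Smc3-wt replicates 1 and 3 were also the libraries with a gene-end peak at Kdm5d, Eif2s3y, Uty and Ddx3y, 4 Y-linked genes at which the other 3 libraries had 0. Without Smc3-wt replicate 1 the difference was 0.0338, without Smc3-wt replicate 3 it was 0.0287, and without Smc3-het replicate 2 it was 0.0995. The index counts bp. The mean peak width in equal-size lists was 577 and 632 bp in Smc3-het and 803, 761 and 906 bp in Smc3-wt libraries. With 500 bp windows the difference was 0.0340, and by counts of regions, each at least 50% covered, it was 0.0912 (exact permutation p 0.2 for both). In full lists it was 0.0454 and no longer the highest of the splits (exact permutation p 0.4), and the closest libraries were the Smc3-het pair, at 0.353 against 0.253 for Smc3-wt replicates 1 and 3. Unequal list length limits this index. The full lists covered 15.5 and 20.6 Mb in the Smc3-het pair, but 37.7 and 66.3 Mb in Smc3-wt replicates 1 and 3. The full-list order therefore does not show that the Smc3-het libraries were most alike.

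Of all equal-size regions, 1087 were called in 3 of 3 Smc3-wt and 0 of 2 Smc3-het libraries, and 615 in 2 of 2 Smc3-het and 0 of 3 Smc3-wt libraries. Full lists gave 5652 and 173. Of the 615, 112 (18.2%) were in 0 of 3 full Smc3-wt lists and 120 in 3 of 3. Of the 1087, 942 (86.7%) were in 0 of 2 full Smc3-het lists, but those lists reach little or no further down than the equal-size ones, so the shares do not compare the genotypes. Few lay at gene ends, 9.38% of the Smc3-wt and 12.4% of the Smc3-het regions. Of the Smc3-wt regions within 100 kb of a protein-coding gene, the best-ranked, chromosome 5, 151733759 to 151734706, lay 83.0 kb from Rfc3, which encodes a subunit of the replication clamp loader. The next lay 21.2 kb from Resf1 (chromosome 6, 149287655 to 149288824), inside Acsl5, a long-chain acyl-CoA synthetase gene (chromosome 19, 55283898 to 55284546), 10.1 kb from Irf2bpl (chromosome 12, 86894462 to 86895423), 71.6 kb from Pou1f1, a pituitary transcription factor gene, and inside Stard13 (chromosome 5, 151412185 to 151413985). Regions near Gm35751, Bambi, Gm21119, Lrrc8b, Ccdc6 and Rap2a followed.

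Of the Smc3-het regions within 100 kb of a protein-coding gene, the best-ranked lay 47.3 kb from Smgc (chromosome 15, 91908479 to 91909036), inside the gene Gm10410 (chromosome 14, 4969087 to 4969379), 22.1 kb from Gm8068, 26.1 kb from the muscle myosin gene Myh2 (chromosome 11, 67144750 to 67145121), inside Dytn and 1.34 kb from Duxf3, a gene of a tandem array whose copies share reads. Regions near Tifab, Ift81, Phldb2, Fam76a and Kntc1 followed. Each of these named regions was present in at least 1 of the longer full Smc3-wt lists, those near Smgc, Gm8068, Tifab, Ift81 and Fam76a in 3 of 3. A single region cannot pass a test with 2 against 3 libraries. Other splits of the libraries gave up to 719 regions against 1087 and up to 1532 against 615. Without Smc3-het replicates 1 and 2 and Smc3-wt replicates 1, 2 and 3, in this order, the Smc3-wt count was 1841, 2526, 1835, 2631 and 1793, and the Smc3-het count was 7470 and 8164 without the first and second of these. With equal-size lists of 13442 peaks the order was turned, 382 Smc3-wt and 414 Smc3-het regions, with up to 313 and 503 in the other splits, and again with −log10 q of at least 10, at 267 and 311. With −log10 q of at least 5 there were 542 and 500, and with an overlap of 50% there were 2180 and 519. The thresholds of 10 and 5 left lists of 9947 and 17309 peaks, so list size changed with them.

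**Figure D2:**
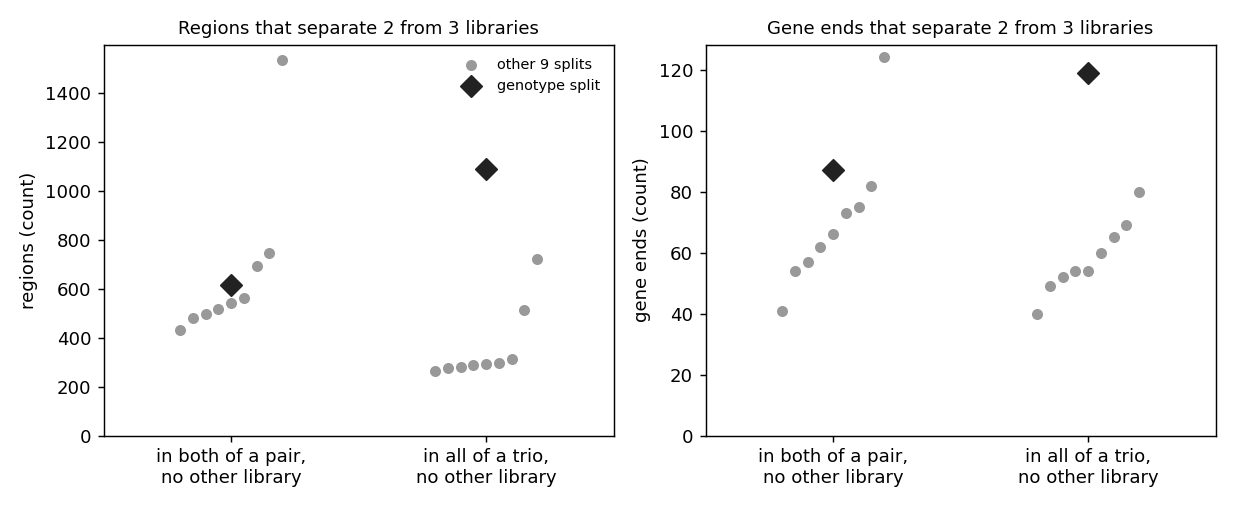
Number of regions (left) and of genes with a peak at an end (right) found in every library of a pair or of the other 3 libraries and in no other library, in equal-size lists. Diamonds are the genotype split and grey points the other 9 splits; the genotype split gives 1087 regions for Smc3-wt, above the others (up to 719), and 615 for Smc3-het, below the highest of the others (1532).

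At gene ends, 119 genes had a peak in 3 of 3 Smc3-wt and 0 of 2 Smc3-het libraries, and 87 the reverse. Of the fixed lists, Car1, the erythroid carbonic anhydrase gene (chromosome 3, 14766214 to 14808365), was the 1 member in the first set. The members in the second set were Ly6c2, a monocyte surface antigen gene, Il2rb, an interleukin receptor gene of T and NK cells, and Nr4a1, an immediate early nuclear receptor gene, each with a gene-end peak in 2 of the 3 full Smc3-wt lists. Of the 87 genes, 3 had none in any full Smc3-wt list, and of the 119, 101 had none in the much shorter full Smc3-het lists. The other splits gave up to 80 and up to 124 genes. Leaving out a library moved the counts by over 1.5 times: 276, 429, 201, 243 and 185 genes for Smc3-wt, and 370, 466, 141, 139 and 152 for Smc3-het, without Smc3-het replicates 1 and 2 and Smc3-wt replicates 1, 2 and 3, in this order. The order was turned under several settings, to 82 and 123 genes with lists of 13442 peaks, 94 and 117 with −log10 q of at least 5, 90 and 150 with at least 10, 103 and 147 by fold, and 124 and 133 with gene ends within 2.5 kb. Under the first 4 of these the Smc3-het count was the highest of the 10 splits, where the others gave up to 90, 84, 93 and 117 genes. Lists of 13442 peaks and both q thresholds, which left 17309 and 9947 peaks, all shorten the lists and are not separate checks. The Smc3-wt count was exceeded by another split with lists of 13442 peaks (94 genes), −log10 q of at least 10 (106) and ranking by fold (117). Full lists gave 587 and 8 genes.

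Among blood lineage genes, megakaryocyte loci held fewer peaks in Smc3-het and loci of core binding factor leukaemia genes held more in lists of 26885 peaks, by amounts that varied with the choice of list. The 18 genes of platelets and their precursors, such as Pf4, Itga2b, Vwf and Gp1ba, had 35 and 38 peaks in Smc3-het and 51, 43 and 48 in Smc3-wt libraries, 36.5 ± 2.12 (SD, n = 2) against 47.3 ± 4.04 (SD, n = 3). Of its first 4 members, Pf4, the platelet factor 4 gene, had 0 and 1 peaks against 3, 3 and 3, and its neighbour Ppbp, another platelet chemokine gene, 0 and 1 against 3, 2 and 3. The windows of these neighbours overlap, so both counts hold many of the same peaks. The integrin genes had 3 and 3 peaks against 3, 2 and 2 at Itga2b, and 5 and 1 against 2, 5 and 3 at Itgb3. Rab27b, a later member, had 1 and 3 against 5, 5 and 8. Much of the list's difference thus lay at Rab27b and at Pf4 with its neighbour Ppbp. Some members went the other way, such as Gp1bb, with 2 and 3 against 2, 1 and 1, and Gp9, with 2 and 3 against 2, 2 and 1. The core binding factor list, with Runx1, Runx2, Flt3 and Gata2, had 69 ± 12.7 against 55.3 ± 11.6, with 78 and 60 peaks against 63, 42 and 61, so that the libraries overlapped. Some of its members, such as Kit and Cd34, had fewer peaks on average in Smc3-het. The two-sided exact permutation p was 0.2 for the megakaryocyte list (adjusted p 0.64) and 0.6 for the core binding factor list (adjusted p 0.64). The megakaryocyte difference of −10.8 peaks was −71.7 in full lists and −2 by fold (exact permutation p 0.6 by fold). Shorter lists also gave smaller differences. It was −2.67 and −1.83 with −log10 q of at least 5 and 10, which left 17309 and 9947 peaks (exact permutation p 0.6 and 0.4). Lists of 13442 peaks gave −2.33 (exact permutation p 0.6). With each peak counted once per list it was −8.67 (exact permutation p 0.2). The core binding factor difference of 13.7 peaks was 1.67 with −log10 q of at least 10, 21.5 by fold and −80.7 in full lists. It was 4.67, 22.7 and 7 without Smc3-het replicate 1, Smc3-het replicate 2 and Smc3-wt replicate 2, in this order.

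Mast cell and basophil loci, with Cpa3 and Fcer1a, had 16.5 ± 3.54 peaks against 21.7 ± 6.03, erythroid loci, with Klf1 and the globin genes, 55 ± 1.41 against 62 ± 6.56, and stem cell loci, with Meis1, Mecom and Hlf, 69.5 ± 13.4 against 79.3 ± 6.51 (SD, n = 2 and 3). Granulocyte-monocyte loci, with Mpo, Elane and Spi1, had 52.5 ± 10.6 against 42.3 ± 7.37. Ly6c2, the member whose gene end separated the genotypes, had 1 and 1 peaks against 1, 0 and 0. The heptad of HSPC transcription factors, Fli1, Erg, Gata2, Runx1, Tal1, Lyl1 and Lmo2, had 41 ± 4.24 against 34.3 ± 6.03, with 7 and 9 peaks at Erg against 9, 4 and 7 and 5 and 1 at Gata2 against 2, 2 and 3. Runx1 and Gata2 are also members of the core binding factor list, so the differences of these lists are not separate results. Cell cycle loci had 44 ± 4.24 against 37 ± 5.57, and immediate early and AP-1 loci, with Fos, Jun and Egr1, 55 ± 2.83 against 48 ± 5.29. The exact permutation p of these 7 lists lay at 0.4 or 0.6, unadjusted. The immediate early and AP-1 difference of 7 peaks was 11.7 with lists of 13442 peaks, 18.5 by fold and 18 with loci extended by 50 kb (exact permutation p 0.2 each). Leaving aside full lists, it ran from 5 to 18.5 over the alternatives, mast cell and basophil from −8 to −2 and granulocyte-monocyte from 2.33 to 17.7. Alternatives turned the direction of the others, with ranges of −14.2 to 2.67 for erythroid, −19.3 to 1 for stem cell, −1.5 to 14.5 for heptad and −1.67 to 10.2 for cell cycle loci. Groups did not overlap for 3 of the 16 lists, where chance gives 20%: the megakaryocyte list, interferon response genes, with 51.5 ± 0.707 against 47 ± 1 (a difference of 4.5, or 2.5 with each peak counted once per list), and cohesin and CTCF genes, with 37.5 ± 0.707 against 42 ± 2, both at an exact permutation p of 0.2. These 2 ran from −2.5 to 8.5 and from −5.5 to 1.33 over the same alternatives.

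The remaining lists overlapped between genotypes. B cell loci had 28 ± 2.83 against 24.3 ± 4.16 peaks, and T and NK cell loci 39.5 ± 4.95 against 38 ± 4.36. Stromal and endothelial loci had 17 ± 2.83 against 15 ± 2, housekeeping loci 49.5 ± 7.78 against 43.7 ± 3.79, and genes of other organs 16 ± 5.66 against 12 ± 1.73 (exact permutation p 0.4, 0.8, 0.6, 0.4 and 0.6 for these 5 lists, unadjusted). Leaving aside full lists, the differences of these lists, in this order, ran from −0.667 to 8.83, −2 to 5, −1.17 to 4, 0.333 to 11.3 and 0 to 8 over the alternatives. In all, 5 of the 16 lists had fewer peaks in Smc3-het and 11 had more, and the smallest adjusted p was 0.64. Against matched random lists, the megakaryocyte difference lay at percentile 0.235, mast cell and basophil at 1.41, the heptad at 97.6, granulocyte-monocyte at 98.4 and core binding factor at 99.9. The megakaryocyte difference lay at percentiles 11.0 and 11.5 with −log10 q of at least 5 and 10, 8.13 with lists of 13442 peaks, 15.8 by fold, 2.90 in full lists and 1.44 with loci extended by 50 kb. With −log10 q of at least 5 and 10, 13442 peaks, full lists, ranking by fold and loci extended by 50 kb, in this order, core binding factor lay at 99.97, 66.7, 99.96, 98.5, 100 and 99.5. The heptad lay at 97.8, 13.9, 99.88, 88.7, 100 and 91.0, granulocyte-monocyte at 95.3, 73.7, 90.2, 54.5, 93.7 and 98.2, and mast cell and basophil at 1.79, 0.15, 0, 19.3, 2.84 and 4.61. Immediate early and AP-1 genes, at 94.98 in the lists of 26885 peaks, lay at 98.8, 100, 99.99, 99.98, 100 and 99.9. In full lists 16 of 16 lists had fewer peaks in Smc3-het, as those lists were shorter.

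At gene ends, 7 of the 16 lists had a lower share in Smc3-het, 7 a higher and 2 the same. Immediate early and AP-1 genes had a gene-end peak in 14 and 14 of 14 genes against 13, 12 and 13, and core binding factor genes in 12 and 11 of 16 against 10, 10 and 10 (p 0.2 each, two-sided exact permutation test; smallest adjusted p 1). Granulocyte-monocyte genes had one in 11 and 9 of 25 against 9, 4 and 8, at percentile 98.0 of random lists. Leaving aside full lists, the difference in share ran from 6 to 16 percentage points for granulocyte-monocyte genes over the alternatives. It ran from 5.95 to 27.4 for immediate early and AP-1 genes and from 6.25 to 27.1 for core binding factor genes. In full lists these differences were −15.3, 2.38 and −2.08, in this order. The heptad had one at 5 and 6 of 7 genes against 5, 4 and 4, stem cell genes at 8 and 11 of 25 against 11, 12 and 12, megakaryocyte genes at 7 and 9 of 18 against 9, 8 and 9, and erythroid genes at 11 and 13 of 20 against 13, 12 and 15. B cell genes had 5 and 3 against 3, 3 and 3 of 16, T and NK cell genes 4 and 5 against 4, 2 and 3 of 20, mast cell and basophil genes 2 and 1 against 4, 1 and 3 of 10, and stromal and endothelial genes 4 and 3 against 2, 6 and 4 of 13. Interferon genes had 16 and 15 against 13, 16 and 16 of 21, cohesin genes 11 and 11 against 13, 11 and 13 of 15, housekeeping genes 13 and 13 against 12, 13 and 14 of 15, and genes of other organs 2 and 2 against 2, 3 and 2 of 20. The 15 cell cycle genes had one in 5 of 5 libraries.

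**Figure D3:**
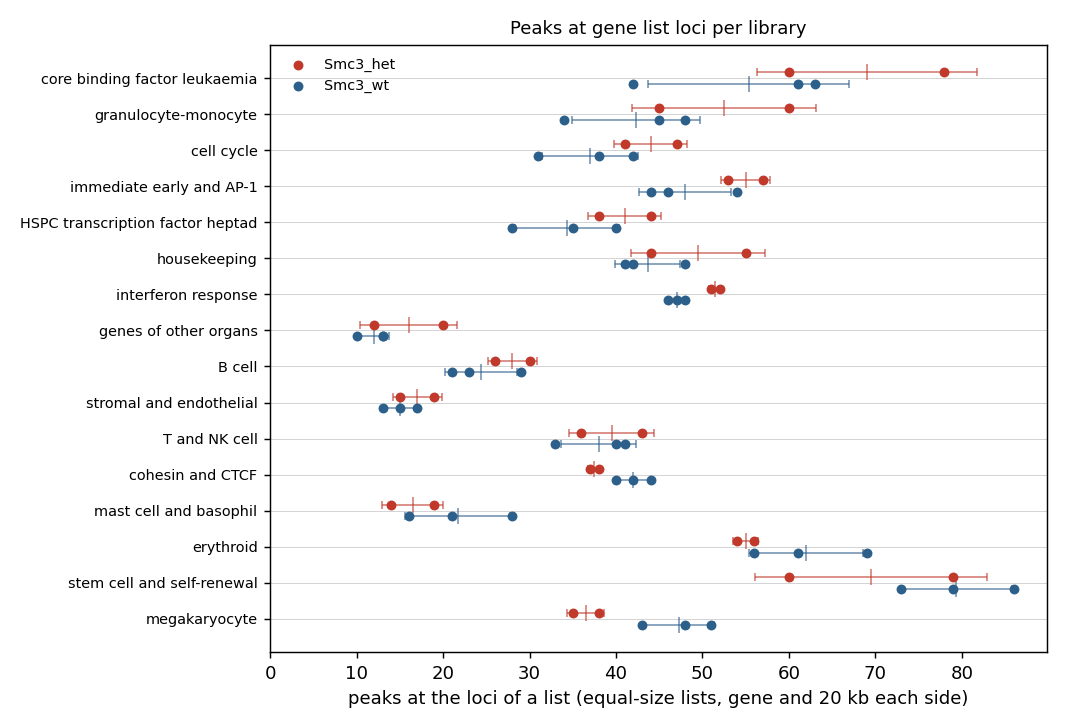
Peaks at the loci of each fixed gene list (gene and 20 kb on each side, equal-size lists), 1 point per library, with group mean and SD (Smc3-het red, n = 2; Smc3-wt blue, n = 3), ordered by the difference of means. Megakaryocyte loci, at the bottom, have 35 and 38 peaks in Smc3-het and 43 to 51 in Smc3-wt libraries; core binding factor loci, at the top, overlap.

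Fli1, which encodes an ETS factor of stem cells and megakaryocytes, had numbers of peaks that overlapped between genotypes once lists were of equal size. The gene (chromosome 9, 32422204 to 32543432) and 100 kb on each side held 10 and 13 peaks in Smc3-het and 15, 6 and 12 in Smc3-wt libraries, 11.5 ± 2.12 (SD, n = 2) against 11 ± 4.58 (SD, n = 3), exact permutation p 1 (two-sided). These peaks formed 27 regions, of which 1, at 32539960 to 32541849 near the gene's higher end, was called in 5 of 5 libraries, and 0 separated the genotypes in either direction. In full lists there were 10 and 17 against 30, 34 and 44 peaks (exact permutation p 0.2), 3 of 72 regions were called in 5 of 5 libraries, and 7 were called in 3 of 3 Smc3-wt and 0 of 2 Smc3-het libraries. The direction in equal-size lists rested on single libraries: the difference in peaks, 0.5 with all libraries, was -1 without Smc3-het replicate 2 and -2 without Smc3-wt replicate 2. It was 2, 2.5 and 1 without Smc3-het replicate 1 and Smc3-wt replicates 1 and 3, 5.5 without both libraries with Y-linked peaks, which leaves 1 Smc3-wt library, 1.17 with −log10 q of at least 5, 3 by fold and 0 with 500 bp windows.

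**Figure D4:**
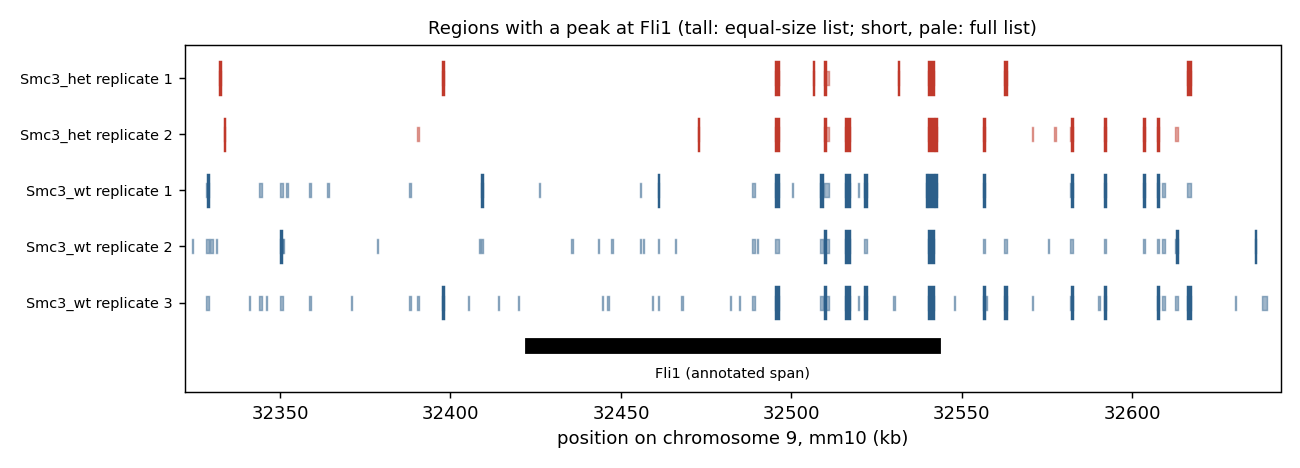
Regions with a peak at Fli1 and 100 kb on each side (chromosome 9, mm10, kb), 1 row per library; tall bars are in the equal-size list and short pale bars in the full list, and the black bar is the annotated gene. The region at 32539960 to 32541849 has a tall bar in 5 of 5 libraries, and the Smc3-wt rows hold more pale bars, 30, 34 and 44 peaks in full lists against 10 and 17.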

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

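Peaks outside the compared chromosomes, on unplaced and unlocalised scaffolds, were in no comparison above. They numbered 96 and 122 in Smc3-het replicates 1 and 2, and 107, 132 and 142 in Smc3-wt replicates 1, 2 and 3, and were singled out only because they are a signal in data not otherwise used. The genotypes overlapped, with a two-sided exact permutation p of 0.4 (n = 2 and 3).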

How the results depend on the processing

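Lower peak number, accessible length, higher gene-end share and higher similarity within genotypes kept their direction under every alternative run, with ranges of −80347 to −52675 peaks and −41.0 to −26.7 Mb over the libraries left out. Motif shares and their alternatives were not run. The q thresholds also changed list size, to 9947 peaks with −log10 q of at least 10 and 17309 with at least 5. With at least 10 there were 311 Smc3-het and 267 Smc3-wt regions, 23 and 3024 in full lists, 150 Smc3-het gene ends and 8 of 16 lists with fewer peaks at loci. With at least 5 there were 542 Smc3-wt regions and, in full lists, 72 Smc3-het regions. List size gave 382 Smc3-wt regions at 13442 peaks and, in full lists, 173 Smc3-het and 5652 Smc3-wt regions, 8 and 587 gene ends, 16 lists lower at loci, 13 lower at gene ends and a Fli1 difference of −22.5 peaks. Ranking by fold gave 147 Smc3-het gene ends and 3 lists lower at loci, an overlap of 50% gave 2180 Smc3-wt regions, gene ends within 2.5 kb gave 133 Smc3-het genes, and 500 bp windows gave a Fli1 difference of 0. The replicate block left out Smc3-wt replicate 3 and used 2 pairs, so fewer libraries. It gave 1793 Smc3-wt regions, 340 Smc3-het regions in full lists and 152 and 185 gene ends. By construction these equal the values without Smc3-wt replicate 3, so the block is not a separate check of them. Same-numbered libraries did not deviate together in their calls (r = −0.00666 over 56749 regions). A single correlation of calls cannot show whether they shared a batch or preparation. Leaving out 1 library gave 891 to 8164 Smc3-het and 1793 to 2631 Smc3-wt regions, 266 to 11749 and 7606 to 12230 in full lists, 139 to 466 and 185 to 429 gene ends, and Fli1 differences of −2 to 2.5; fewer libraries to satisfy raise such counts by construction. Without the 2 libraries with peaks at Y-linked genes, a choice made after the data were seen that leaves 1 Smc3-wt library, there were 1976 Smc3-het and 8949 Smc3-wt regions, 857 and 78140 in full lists, 461 and 552 gene ends and 4 lists lower at gene ends. The share of peaks between genes, 0.17 points higher in Smc3-het, was turned to −0.402 and −0.632 with the stricter q thresholds, −0.750 at 13442 peaks, −11.3 in full lists, −0.986 by fold, −0.249 with the block and −0.962 to 1.30 over the libraries left out, and the gene-body difference, −0.693, ran from −1.54 to 0.155 over the libraries left out. The cause was not tested where none is given. Of the other values, 346 moved by less than the spread between replicates or kept direction and 112 moved by more, none of which had passed a test. Depth was not given as a fragment count, and a region missing from a list is not shown to be closed.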

Other observations

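The regions named in this paragraph were chosen after their values were seen. At the megakaryocyte loci, 4 regions were called in 3 of 3 Smc3-wt and 0 of 2 Smc3-het libraries, where the share over all regions gives 1.57, and 0 the reverse. They lay inside Vwf, the von Willebrand factor gene (chromosome 6, 125564729 to 125565608), inside Rab27b (chromosome 18, 70021510 to 70022728 and 70102548 to 70103458) and at an end of Cxcl3, a chemokine gene (chromosome 5, 90785459 to 90786525), 12.6 kb from Pf4 and 15.9 kb from Ppbp. In the counts of alternatives below, the replicate block repeats the values without Smc3-wt replicate 3. The peak difference at these loci was negative under 14 of 14 alternatives, but full lists, at −71.7, gave 16 of 16 lists fewer peaks. With 500 bp windows it was −10.2, at percentile 0.235 of matched random lists, whereas −log10 q of at least 10, lists of 13442 peaks and ranking by fold put −1.83, −2.33 and −2 at percentiles 11.5, 8.13 and 15.8. Mast cell and basophil loci had 3 such regions, 2 of them at Cpa3, the carboxypeptidase gene of mast cells, where 0.843 would be given by the share over all regions, and a negative difference under 14 of 14 alternatives, from −31.7 in full lists to −2 without Smc3-wt replicate 1. Loci of T and NK cell genes had 5 regions in each direction, against 1.32 and 0.748, and the Smc3-wt ones lay at Cd247 and Gata3. The heptad and core binding factor lists had 0 in either direction, and the core binding factor difference was positive under 13 of 14 alternatives, at 1.67 with −log10 q of at least 10, and turned to −80.7 in full lists.

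Some items were chosen after their values were seen. Regions in both Smc3-het and no Smc3-wt equal-size list lay 3.12 kb from Hoxb4 (chromosome 11, 96314899 to 96315396), absent from the full Smc3-wt lists, and between Hoxa5 and Hoxa7 (chromosome 6, 52212888 to 52213417), present in 1 of them. Gene ends with a peak in both Smc3-het and no Smc3-wt equal-size list also included Ccl2, Ifitm3, Il18, Siglech and Kdm6b, each with a gene-end peak in 1 or 2 of the full Smc3-wt lists. Those of the opposite kind included Alox5ap and Plac8, each with one in the full list of Smc3-het replicate 2, and Mpeg1, Tlr3, Tap2 and Kdm6a.

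Of the tests below, those on mapped fragments, satellite fragments, other splits and the sex of the mice were chosen after the result was seen. The shorter Smc3-het lists were weighed against 3 technical explanations. Fewer mapped fragments would lower background coverage, but its mean was 1.27-fold that of Smc3-wt. If duplicates were kept, this coverage counts them too, so fewer distinct fragments in Smc3-het could be missed and stay open. A lower signal over background may be the source, since the median pileup over background at regions of 5 of 5 libraries was 0.455 times that of Smc3-wt and lower in both Smc3-het than in every Smc3-wt library. More fragments at the satellite repeat on chromosome 2 (98666556 to 98667313), whose pileup over background was 1.52-fold that of Smc3-wt, are consistent with the same. An effect of Smc3 dosage on accessibility itself stays open and was not tested apart from these.

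Of the 10 splits, 1 gave as many as the 1087 regions of Smc3-wt, the genotype split itself, and the highest other gave 719. As many as the 615 of Smc3-het were given by 4, with 1532 the highest. For gene ends, 1 gave as many as 119 (highest other 80) and 2 as many as 87 (highest other 124). With lists of 13442 peaks another split exceeded the Smc3-wt gene ends, 94 against 82. So it did with −log10 q of at least 10, 106 against 90, and by fold, 117 against 103. With 10 splits no share under 0.05 is possible. For the 1087 regions, a linked difference along the chromosomes would crowd them, but 50.6% had another within 500 kb, under the upper bound of 1000 matched draws, 57.6%. The share was taken over the whole genome, where the draws averaged 54.4%. A linked segment holding few of the regions could not be seen in it and stays open. Sex would need Y-linked peaks in Smc3-wt replicate 2, which had them at 0 of 4 genes. Peaks near the end of the equal-size lists were considered as well. The median lowest percentile of the regions was 21.3, not above the highest of the other sets of 3 libraries, 24.1, though above the next, 20.4. The set at 24.1 joined both Smc3-het libraries with Smc3-wt replicate 2. Percentiles are ranks within lists cut at different strengths, and the full Smc3-wt lists reach far below the cut. The comparison thus cannot tell whether the regions are weak peaks. With the lower Smc3-het signal, weak peaks stay open as an explanation beside an effect of Smc3 dosage, which was not tested apart from it.

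In equal-size lists, Smc3-wt replicates 1 and 3 alone shared 1532 regions, more than any other pair, which may point to a structure of the samples other than genotype, though in full lists, of unequal length, replicates 2 and 3 shared more, 6638 against 5705. Kdm5d, Eif2s3y, Uty and Ddx3y, on the Y chromosome, had a gene-end peak in replicates 1 and 3 and in 0 of the other 3 libraries, so replicates 1 and 3 may come from male mice. Smc3-wt replicate 2 lacked such peaks at a signal over background of 26.5, above the 25.1 of replicate 1, and X held 4.48% of its peaks against 2.04% and 2.25% in replicates 1 and 3 (2.95% against 2.31% and 2.38% in equal-size lists). In Smc3-het replicates 1 and 2, of lower signal, X held 1.98% and 3.05% (1.98% and 2.73% in equal-size lists). Peaks within Xist, an RNA gene on X, had the reverse pattern to the Y-linked genes. Full lists held 1 and 1 in Smc3-het replicates 1 and 2 and 4 in Smc3-wt replicate 2, against 0 and 0 in Smc3-wt replicates 1 and 3. These few peaks do not settle the sex of the Smc3-het libraries, and sex may be unevenly spread over the genotypes. The sex chromosomes held few of the 1532 regions, 2.87% on X or Y against 2.61% of all regions, and an effect of sex on autosomes, or a shared preparation, was not tested.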
